A study of Mus musculus with 8 samples.

How the data were processed

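Single-cell RNA sequencing was done on live T cells carrying the alpha-beta T-cell receptor and CD4, sorted from the colonic lamina propria of C57BL/6 mice 3 weeks old. There were 8 libraries in 4 groups of 2, and the labels call each library a biological replicate. The groups were Cre-negative controls, mice in which CD4-Cre acts on a floxed Prdm1 gene (Prdm1 cKO), mice in which it acts on a floxed Maf gene (Maf cKO), and mice with both floxed genes (DKO). CD4-Cre is a transgene that deletes floxed DNA in cells that express Cd4. The labels give 7000 cells loaded per library and 1300 to 2100 recovered, and the files held 1584 to 2341 barcodes per library.

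The deposited values were raw UMI counts per gene and cell. A UMI is a sequence tag that marks 1 captured RNA molecule. Per the submitters' processing notes, the authors made these counts with Cell Ranger (no version stated) on the mm10 mouse genome from 10x 3' libraries. The 8 files listed 27998 genes and 15851 barcodes already called as cells, with 71762351 UMIs. Gene identifiers were kept apart where 2 identifiers shared a symbol, which 56 symbols did. The values were checked to be whole numbers with a different total in each library.

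Groups came from the labels. A cell was kept with at least 500 genes detected and at most 10% of its UMIs from the mitochondrial genome, which removed 172 barcodes and left 15679. A cell was also removed when it carried UMIs of at least 2 different genes of a B-cell, myeloid, epithelial or stromal list, which removed 3488. The remaining 12191 cells held 48581239 UMIs. Scrublet (scanpy 1.11.5), given a doublet rate of 5%, called 20 of the kept cells (0.16%), which is too few for a working doublet call at that rate. Leaving out the 5% of cells with the highest scores of each library (428 kept cells) was added as an alternative.

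Cells were clustered by the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 1) on a graph of 15 nearest neighbours in 30 principal components of 2000 variable genes. Prdm1, Maf, Il10, receptor segment, sex-linked and mitochondrial genes were left out of the variable genes. A cluster took the name of a marker list when at least 3 of its markers were at least 1.5 times the level in the other cells, with an offset of 20 CPM (UMI counts scaled to a common library total), and the list led among the cluster's top 10 genes. The marker lists were fixed before the data were examined, and the rule that turned markers into a name was set afterwards. Classes of cells with over 60% of their cells from 1 group were not compared by genes. Cells outside the naive-like, Treg-like and other-lineage clusters made up the non-Treg non-naive cells. Macrophage-like cells were removed cells with UMIs of all 3 C1q genes, and they were compared separately.

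Genes were tested on UMI counts summed per library, with the library and not the cell as the replicate. The test was the edgeR quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with robust spread, TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. All 8 libraries entered each fit, which left 4 residual degrees of freedom, so the spread was shared over the groups. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of F. The interaction contrast asked whether the DKO differed from the sum of both single knockouts on the log2 scale. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.33, so none was used. CPM means of groups are after TMM scaling unless given per library, those of macrophage-like cells are without TMM, and errors after them are SD over 2 libraries.

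Fixed gene lists (33 in all) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry beside it. Adjustment was over the 25 lists with at least 3 tested genes. The 8 lists with fewer were sex-linked, CD8 T, gamma-delta T and NKT, B cell, plasma cell, granulocyte or mast, epithelial, and stromal or endothelial genes. Numbers of cells per class were tested with edgeR quasi-likelihood against the kept cells per library, for the 6 named classes with at least 50 cells. The share of cells with an Il10 UMI was taken after thinning each cell to 1500 UMIs, since detection rises with depth. It is a value without a test, and naive-like cells gave the background. The Prdm1 and Il10 levels expected from shares alone were each cluster's control level weighted by the library's UMI shares, over clusters with at least 20 cells in each control library, at resolutions 0.6, 1.0 and 1.4. Counting intervals of ratios are 95% and cover counting error only.

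Genes named in the text followed a rule fixed before the data were examined. It took Prdm1, Maf and Il10, a panel of 14 genes (among them Foxp3, Il17a, Ifng, Gata3, Tbx21, Bcl6, Tcf7, Lag3, Havcr2, Tigit, Pdcd1, Ctla4 and Icos), and up to 4 members of each list with the smallest p. It added the 8 largest rises and the 8 largest falls of each comparison with control. These had to be past the threshold, with a mean of at least 20 CPM and no overlap between the groups, leaving out receptor segment, mitochondrial, ribosomal, sex-linked and unnamed genes. Within cell classes and in the other contrasts, the 5 largest rises and falls were taken. The comparisons, tests, lists and most alternatives were also set before the data were examined. Other members of lists are named where they were among those past the threshold, and not every gene that the rule took is named.

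Alternatives covered scaling (library totals, RLE), gene filtering, DESeq2 1.42.0, fits of 2 groups, a replicate block, cell filters (200 or 1000 genes, 5% mitochondrial), other lineages kept, doublets and a 1.5-fold minimum. They also covered limma on the mean of per-cell CPM with 10 CPM added, Leiden resolutions 0.6 and 1.4, Treg cells defined by a Foxp3 UMI, thinning depths, and each library left out in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. Naive-like cells left out was added after the class shares were seen.

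The pipeline was tested on simulated genes changed by known amounts. At a 1.5-fold change it recovered 74.6% of changed genes in the Prdm1 cKO and Maf cKO designs and 80.6% in the DKO design. At a 2-fold change it recovered 98.5%, 98.5% and 100%, and 4.7% to 5.6% of calls were false. With nothing changed edgeR made 0 calls and 0 of 30 random lists passed, which did not test lists of correlated genes. The share test recovered 42% of 2-fold changes in DKO and called 0.8% of unchanged classes in 50 sets. Shares that did not pass may have changed 2-fold. Other software was Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6.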

Results

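Transcripts were counted in single CD4 T cells of the mouse colon in 8 libraries, 2 for each of the control, Prdm1 cKO, Maf cKO and DKO groups. The series title concerns the network of regulators that controls IL-10, an anti-inflammatory cytokine, in helper T cells. After filtering, the control libraries held 1188 and 1267 cells with 3827109 and 3775456 UMIs. The Prdm1 cKO libraries held 1552 and 1217 cells with 5229243 and 4217066 UMIs, and the Maf cKO libraries 1347 and 1782 cells with 5586832 and 6593331 UMIs. The DKO libraries held 1833 and 2005 cells with 8924252 and 10427950 UMIs. The median depth per kept cell was 2829 ± 66.1 UMIs in control, 3053 ± 9.55 in Prdm1 cKO, 3131 ± 161 in Maf cKO and 4219 ± 22.6 in DKO (SD, n = 2). Cells with UMIs of the macrophage complement genes C1qa, C1qb and C1qc made up 13.7% ± 3.32, 16.5% ± 4.88, 10.7% ± 1.13 and 5.55% ± 1.63 of the barcodes that passed the quality filter in control, Prdm1 cKO, Maf cKO and DKO (SD, n = 2). They were left out of the T-cell comparisons.

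The floxed genes and Il10 were read first. Maf, which encodes the transcription factor c-Maf (ENSMUSG00000055435, GRCm38 chromosome 8, 115682942 to 115707794, minus strand), was at 70.5 and 121 CPM in the control libraries and at 138 and 166 CPM in the Prdm1 cKO libraries. It had 4 UMIs over both Maf cKO libraries and 6 over both DKO libraries, against 728 in control. Scaled to library UMIs, control Maf was 291.6 times that in Maf cKO (95% counting interval 113 to 1070). It was 309 times that in DKO (141 to 844). Prdm1, which encodes the repressor Blimp-1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501, minus strand), was at 5.75 and 6.09 CPM in control. Libraries labelled Prdm1 cKO were at 59.7 and 78.5 CPM and those labelled DKO at 206 and 183. Scaled to UMIs, that was 11.5 (8.49 to 15.9) and 32.7 (24.4 to 44.9) times control. These libraries read the 3' end of transcripts, so the counts do not show whether the floxed part of Prdm1 was deleted. Prdm1 also rose in Maf cKO, to 17.9 and 17.4 CPM (log2 1.44 ± 0.21 SE, edgeR quasi-likelihood, adjusted p = 0.00016). Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974, plus strand) was at 56.4 and 136 CPM in control, 19.5 and 16.6 in Prdm1 cKO, 73.2 and 76.3 in Maf cKO, and 3.25 and 3.74 in DKO. Foxp3, which encodes the factor that defines regulatory T (Treg) cells (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), is described with each comparison.

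**Figure D1:**
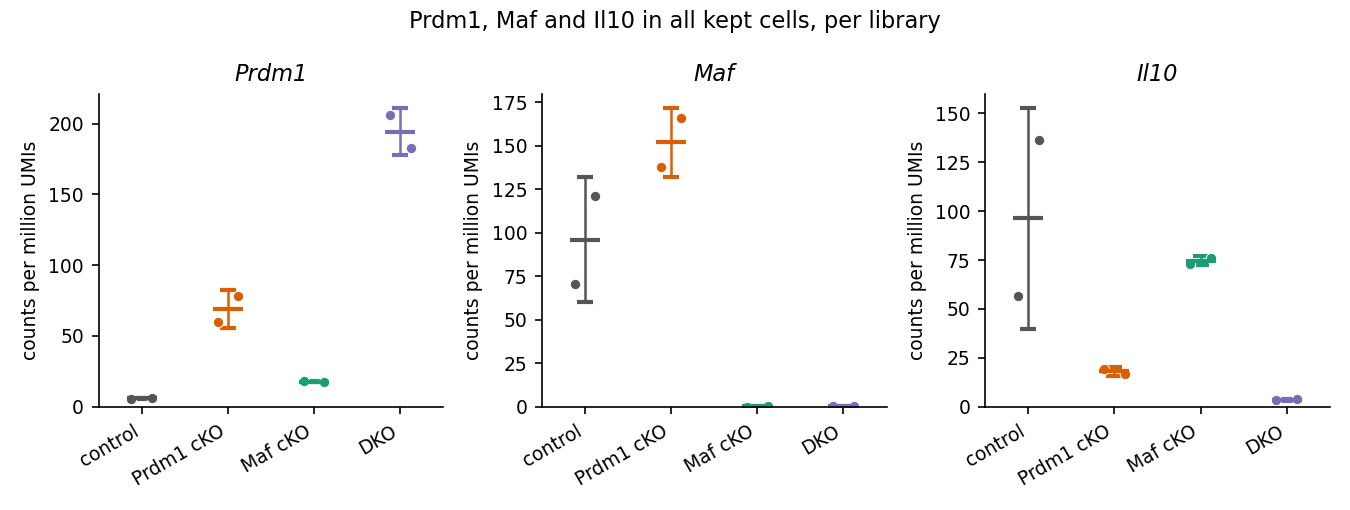
Counts per library of Prdm1, Maf and Il10 in all kept cells, in CPM of the library total for the 4 groups; points are libraries, and bars show the mean and SD of 2 libraries. Both DKO libraries lay under 4 CPM for Il10, against 56.4 and 136 CPM in the control libraries.

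The comparison of Prdm1 cKO with control asked which transcripts of colonic CD4 T cells change when the Prdm1 gene is targeted. Cxcr5, the chemokine receptor that draws cells into B-cell follicles, rose 9.57-fold (log2 3.26 ± 0.24 SE, adjusted p = 4.53e-07), from 4.97 to 47.9 CPM with 2 libraries per group. Gzmb, which encodes the cytotoxic protease granzyme B, fell 34.4-fold (log2 -5.10 ± 0.29, adjusted p = 0.000392), from 199.4 to 5.85 CPM. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 229 of 10221 tested genes changed, 137 up and 92 down, and 151 of them by at least 1.5-fold. The count was 66 without control replicate 1, 121 without control replicate 2, 357 without Prdm1 cKO replicate 1 and 90 without Prdm1 cKO replicate 2.

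Further genes passed in Prdm1 cKO. Tox2, a nuclear factor of follicular helper T (Tfh) cells, which help B cells make antibody, rose by log2 2.52 ± 0.26 (adjusted p = 0.000392), and Pdcd1, which encodes the inhibitory receptor PD-1, by 1.24 ± 0.15 (adjusted p = 0.000169). Sh2d1a, which encodes the adaptor SAP needed for T-cell help to B cells, rose by 1.05 ± 0.10 (adjusted p = 8.12e-06). Ccr6, a chemokine receptor of Th17 cells (helper cells that make IL-17), rose by 2.24 ± 0.26 (adjusted p = 8.41e-05). The falls included Cxcr6, a chemokine receptor of tissue effector cells, at -1.25 ± 0.15 (adjusted p = 0.000175). Txnip, an inhibitor of glucose uptake, fell by log2 -0.95 ± 0.11 (adjusted p = 8.41e-05), but not when cells of other lineages were kept (-0.52, adjusted p = 0.133). Ctla2a, a protease inhibitor gene, fell by log2 -1.49 ± 0.22 (adjusted p = 0.00942), with adjusted p = 0.155 by limma on the mean of per-cell CPM. Pmaip1, which promotes cell death, rose by 0.98 ± 0.14 (adjusted p = 0.000557), with adjusted p = 0.158 when other lineages were kept.

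Il10 itself did not pass the test in Prdm1 cKO (log2 -2.43 ± 0.51, adjusted p = 0.145). The control libraries were at 56.4 and 136 CPM and the Prdm1 cKO libraries at 19.5 and 16.6 CPM. Without control replicate 1 it was at -2.93 and without control replicate 2 at -1.68. No call is drawn from these fits, since they drop the spread between the control libraries. By DESeq2 it passed with all libraries (-2.45, adjusted p = 5.77e-05). Of the fixed panel, Foxp3 (0.16 ± 0.15, adjusted p = 0.716), Gata3, the factor of Th2 cells (-0.15, adjusted p = 0.553), Ctla4 (-0.14, adjusted p = 0.779) and Icos (-0.03, adjusted p = 0.944), which encode an inhibitory and a costimulatory receptor, did not pass. Nor did Ifng, the cytokine of Th1 cells (0.47, adjusted p = 0.753), or Il17a (-1.56 ± 0.87, adjusted p = 0.54). Bcl6, the lead factor of Tfh cells, passed at 1.83 ± 0.46 (adjusted p = 0.0404), but not in 6 of the 8 fits that left out a library. Its adjusted p was 0.241 and 0.172 without control replicates 1 and 2, 0.0987 and 0.109 without Prdm1 cKO replicates 1 and 2, and 0.0503 and 0.0512 without DKO replicates 1 and 2.

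Among the fixed lists, 10 of 25 passed camera in Prdm1 cKO, 5 up and 5 down. In the Tfh list, 8 of 14 tested genes rose and 0 fell by edgeR (12 adjusted over the list alone): Cxcr5, Sh2d1a, Pdcd1, Tox2, Slamf6, P2rx7, Tox and Bcl6 (camera adjusted p = 6.94e-29; adjusted p = 0.0815 with an estimated correlation; fry adjusted p = 0.0372). In the list of naive and central memory genes, which mark cells that circulate through lymphoid organs, 5 of 17 fell (9 adjusted over the list alone), among them Klf2, Satb1, Klf3 and Bcl2 (adjusted p = 1.02e-07; adjusted p = 0.51 with an estimated correlation). Klf2, which controls exit from lymphoid tissue, fell by log2 -0.55 ± 0.09 (adjusted p = 0.00265), with adjusted p = 0.113 at a minimum of 1000 genes per cell and 0.154 with other lineages kept. The transcription factor list moved up (9 of 25 rose, Prdm1 itself among them, 2 fell, 14 adjusted over the list alone; adjusted p = 1.02e-07; adjusted p = 0.433 with an estimated correlation). The NF-kB list did too (2 of 19 rose, 5 adjusted over the list alone; adjusted p = 0.000303; adjusted p = 0.66 with an estimated correlation; adjusted p = 0.746 without naive-like cells). Cholesterol synthesis moved down (1 of 16 fell, Idi1; 6 adjusted over the list alone; adjusted p = 2.07e-05; adjusted p = 0.51 with an estimated correlation).

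Smaller list shifts in Prdm1 cKO depended on single libraries or on the cells kept. The list of intestinal Treg genes moved down (3 of 17 fell, among them Gzmb and Il1rl1, while Nfil3 and Rora rose; 10 adjusted over the list alone; adjusted p = 3.4e-06; adjusted p = 0.51 with an estimated correlation), with adjusted p = 0.0996 without Prdm1 cKO replicate 1. The cytotoxic list moved down (Gzmb and Gzmc of 14 fell, 3 adjusted over the list alone; adjusted p = 0.00175; adjusted p = 0.525 with an estimated correlation) and turned up without Prdm1 cKO replicate 1 (adjusted p = 0.622). Tissue residence genes moved down (3 of 15 fell, 1 rose, 4 adjusted over the list alone; adjusted p = 0.00451; adjusted p = 0.51 with an estimated correlation), with adjusted p = 0.0905 without control replicate 2 and 0.132 without Prdm1 cKO replicate 1. Cell cycle genes moved up (1 of 22 rose, Mcm6, and 1 adjusted over the list alone; adjusted p = 0.00689; adjusted p = 0.79 with an estimated correlation), with adjusted p = 0.42 without control replicate 2 and 0.102 without Prdm1 cKO replicate 2. With other lineages kept, the cell cycle list moved down (adjusted p = 0.0356), and it pointed down without naive-like cells (adjusted p = 0.263). Glycolysis moved up with 0 of 16 genes past the threshold by edgeR (4 adjusted over the list alone; adjusted p = 0.000617; adjusted p = 0.588 with an estimated correlation), and had adjusted p = 0.0838 without Prdm1 cKO replicate 2.

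The other 15 lists did not pass camera in Prdm1 cKO. Of the Th17 genes 4 of 16 rose, Ccr6, Rora, Il23r and Irf4 (9 adjusted over the list alone, adjusted p = 0.065), and of the IL-10 and co-inhibitory receptor genes 2 of 14 rose, Pdcd1 and Nt5e, and Ctla2a fell (6 adjusted over the list alone, adjusted p = 0.267). The chemokine list held 2 rises and 2 falls among 20 genes (9 adjusted over the list alone, adjusted p = 0.919). The lists of effector cytokines (adjusted p = 0.0689), Th1 (0.437), Th2 (0.773), Treg core (0.516), interferon response (0.145), immediate early (0.267), IL-2 and STAT5 (0.34), survival (0.633), oxidative phosphorylation (0.0689), mitochondrial genome (0.328), ribosomal protein (0.267) and myeloid genes (0.578) did not pass either. Of these, Th1 (adjusted p = 0.000229), Th2 (0.0477), Treg core (6.68e-06), chemokine (0.018), interferon response (2.43e-08) and immediate early genes (0.0477) passed downward, and ribosomal protein genes upward (8.69e-05), without naive-like cells. The last passed downward without Prdm1 cKO replicate 1 (0.031). Calls gained without control replicate 1 were IL-10 and co-inhibitory receptors (0.0191), chemokines (0.00066), immediate early genes (0.0141) and the mitochondrial genome (0.0448), all downward, and oxidative phosphorylation upward (0.00113). Effector cytokines (0.0047 and 0.0426), Th17 (0.0203 and 0.000785) and oxidative phosphorylation (0.04 and 0.0426) passed upward without Prdm1 cKO replicate 1 and with other lineages kept. Without Prdm1 cKO replicate 2, Th1 (0.00022), interferon response (0.0155) and immediate early genes (0.00587) passed downward, the last also with other lineages kept (0.0214). For Th2 the median (0.24) was positive while the mean (-0.06) and the test were negative. For IL-2 and STAT5 the mean (0.03) was positive while the median (-0.14) and the test were negative. For chemokines, camera pointed down and fry up. Camera with an estimated correlation called 0 lists in Prdm1 cKO (2 at an unadjusted p under 0.05), 0 in Maf cKO (4) and 0 in DKO (1), while fry called 1, 13 and 11.

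The comparison of Maf cKO with control asked which transcripts change when c-Maf is absent. Ccl5, a chemokine of effector T cells, rose 8.29-fold (log2 3.05 ± 0.21, adjusted p = 0.000357), from 162 to 1343 CPM, and Gzmb rose 5.37-fold (2.43 ± 0.19, adjusted p = 0.00028), with 2 libraries per group. Itgae, which encodes the integrin CD103 that holds T cells at the epithelium, rose 8.16-fold (3.03 ± 0.16, adjusted p = 6.13e-10), from 9.93 to 81.4 CPM. Tcf7, which encodes the stem-like and memory factor TCF-1, fell 2.03-fold (-1.02 ± 0.13, adjusted p = 0.000286). By edgeR quasi-likelihood 1883 of 10221 tested genes changed, 1058 up and 825 down, and 984 of them by at least 1.5-fold. The count was 739 without control replicate 2, 971 without Maf cKO replicate 1 and 1056 without Maf cKO replicate 2, and it was 386 when naive-like cells were left out. Scaling by library totals alone in place of TMM shifted the median log2 fold change of all genes from -0.011 to 0.127 in this comparison.

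Further genes passed in Maf cKO, also under each left-out library and with naive-like cells left out. Cxcr3, the chemokine receptor of Th1 cells, rose by log2 1.57 ± 0.16 (adjusted p = 0.000127). Il2rb, a receptor chain for IL-2 and IL-15, rose by 1.27 ± 0.14 (adjusted p = 9.95e-05). The interferon-induced genes Ifi27l2a (0.89 ± 0.08, adjusted p = 9.64e-07), Isg20 (1.18 ± 0.15, adjusted p = 4.1e-05) and Zbp1 (0.74 ± 0.10, adjusted p = 6.31e-05) rose. So did Hmgb2 of dividing cells (0.82 ± 0.10, adjusted p = 2.36e-05). The falls included Bach2, a repressor that keeps T cells undifferentiated (-1.28 ± 0.17, adjusted p = 4.86e-05), and Bcl2, which protects from cell death (-1.21 ± 0.12, adjusted p = 4.1e-05).

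Some changes in Maf cKO were not past the threshold once naive-like cells were left out. Foxp3 rose 2.02-fold in all cells (log2 1.01 ± 0.14, adjusted p = 0.000248) and was at 0.28 (adjusted p = 0.304) without naive-like cells. The IL-2 receptor gene Il2ra went from 0.81 to 0.08 (adjusted p = 0.816), Cxcr6 from 0.62 ± 0.13 to -0.15, and Cst7, an inhibitor of lysosomal proteases in cytotoxic cells, from 1.89 ± 0.27 to 1.28 (adjusted p = 0.149). The naive gene Lef1 (-0.88) and the ribosomal protein gene Rps19 (-0.59 ± 0.07, adjusted p = 1.56e-05) likewise did not pass without naive-like cells, at -0.43 (adjusted p = 0.17) and -0.23 (adjusted p = 0.193). Il10 did not pass in Maf cKO (-0.50 ± 0.42, adjusted p = 0.497), and no call is drawn without control replicate 1 (-0.99). Also not past the threshold were Tbx21, the factor of Th1 cells (1.04, adjusted p = 0.058; past it at 1.05 without Prdm1 cKO replicate 1 or 2 and at 1.04 without DKO replicate 1 or 2), and Gata3 (-0.03, adjusted p = 0.881). Pdcd1 (0.09, adjusted p = 0.754; -0.65, adjusted p = 0.0193 without naive-like cells), Icos (-0.06, adjusted p = 0.71) and Il17a (-0.32, adjusted p = 0.814) did not pass. C1qc, a macrophage gene, fell (-1.69 ± 0.28, adjusted p = 0.000345), which measures remaining macrophage RNA in the kept cells, and did not pass with other lineages kept (-0.83, adjusted p = 0.109).

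In Maf cKO 18 of 25 lists passed camera, 13 up and 5 down. Upward lists with an adjusted p = 0.178 with an estimated correlation were these. Cytotoxic genes rose in 8 of 14 (9 adjusted over the list alone; adjusted p = 1.08e-12), among them Ccl5, Fasl and Gzmb, and Th1 genes in 7 of 16 (8 adjusted over the list alone; adjusted p = 1.09e-10). Interferon response genes rose in 15 of 24 (17 adjusted over the list alone; adjusted p = 3.52e-14), cell cycle genes in 18 of 22 (20 adjusted over the list alone; adjusted p = 1.34e-19) and glycolysis genes in 9 of 16 (13 adjusted over the list alone; adjusted p = 4.47e-08). Without naive-like cells 6 of 23 interferon response, 5 of 22 cell cycle, 1 of 16 glycolysis, 3 of 14 cytotoxic and 3 of 16 Th1 genes rose. Treg core genes rose in 10 of 20 and fell in 1, Gpr83 (14 adjusted over the list alone; adjusted p = 8.93e-07). Without naive-like cells that list pointed down (adjusted p = 0.354). Of the IL-10 and co-inhibitory receptor genes 6 of 14 rose, Ctla2a, Cd274, Cd5, Havcr2, Entpd1 and Ctla4 (8 adjusted over the list alone; adjusted p = 0.000102), but not Il10, and the list did not pass without naive-like cells (adjusted p = 0.513). Tissue residence genes rose in 5 of 15 and fell in 1 (9 adjusted over the list alone; adjusted p = 0.000637; adjusted p = 0.199 without naive-like cells).

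The downward lists in Maf cKO, also with an adjusted p = 0.178 with an estimated correlation, were naive and central memory genes (14 of 17 fell, 16 adjusted over the list alone; adjusted p = 2.8e-20), ribosomal protein genes (27 of 28 fell, 28 adjusted over the list alone; adjusted p = 7.65e-18) and the mitochondrial genome (11 of 13 fell, 12 adjusted over the list alone; adjusted p = 3.26e-10). Scaled by library totals, 20 ribosomal and 9 mitochondrial genes fell, and with naive-like cells left out 1 and 3 did. In that setting 7 of 17 naive and central memory genes fell. The remaining lists had larger p with an estimated correlation. Intestinal Treg genes moved up (6 of 17 rose, 7 adjusted over the list alone; adjusted p = 5.31e-06; adjusted p = 0.274 with an estimated correlation; adjusted p = 0.898 without naive-like cells). Oxidative phosphorylation moved up (9 of 22 rose, 11 adjusted over the list alone; adjusted p = 0.000216; adjusted p = 0.448 with an estimated correlation), as did NF-kB genes (8 of 19 rose, 1 fell, 10 adjusted over the list alone; adjusted p = 0.00289; adjusted p = 0.466 with an estimated correlation; pointing down with adjusted p = 0.245 without naive-like cells).

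Another 4 lists in Maf cKO depended on single libraries or on the setting. Chemokine genes moved up (4 of 20 rose, 3 fell, 7 adjusted over the list alone; adjusted p = 0.00521; adjusted p = 0.377 with an estimated correlation), with adjusted p = 0.629 without control replicate 1, 0.154 without Maf cKO replicate 1, 0.148 with other lineages kept and 0.513 without naive-like cells. Cholesterol synthesis moved up (3 of 16 rose, Sqle, Hmgcs1 and Fdft1, 3 adjusted over the list alone; adjusted p = 0.00238; adjusted p = 0.387 with an estimated correlation), with adjusted p = 0.0572 without control replicate 2. Immediate early genes moved down (3 of 21 fell, 3 adjusted over the list alone; adjusted p = 0.0203; adjusted p = 0.565 with an estimated correlation), with adjusted p = 0.233 without control replicate 2 and 0.0714 without Maf cKO replicate 2. Myeloid genes moved down (C1qc, C1qa and C1qb of 9 fell and Cst3 rose, 5 adjusted over the list alone; adjusted p = 0.0419; adjusted p = 0.377 with an estimated correlation). Cst3 was at -0.04 (adjusted p = 0.871) with other lineages kept. Their adjusted p was 0.0572 and 0.0692 without control replicates 1 and 2, 0.0995 and 0.101 without Prdm1 cKO replicates 1 and 2, 0.143 without Maf cKO replicate 2, 0.245 without naive-like cells and 0.0547 with a replicate block. Lists of effector cytokines (1 of 11 rose; adjusted p = 0.429), Th17 (1 of 16 rose, 1 fell; 0.475), Th2 (2 of 8 rose; 0.161), Tfh (1 of 14 rose, 4 fell; 0.233), IL-2 and STAT5 (3 of 15 each way; 0.801), survival (5 of 15 rose, 3 fell; 0.429) and transcription factor genes (8 of 25 rose, 6 fell; 0.654) did not pass. Of these, Th17 (adjusted p = 0.003), Tfh (3.23e-06) and transcription factor genes (0.000132) passed downward without naive-like cells. Tfh genes did so without control replicate 1 (0.0396), and transcription factor genes passed upward with other lineages kept (0.0436). For Th17 the mean (-0.04) and for transcription factors the mean (-0.14) were negative while the median (0.05 and 0.40) and the test were positive.

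**Figure D2:**
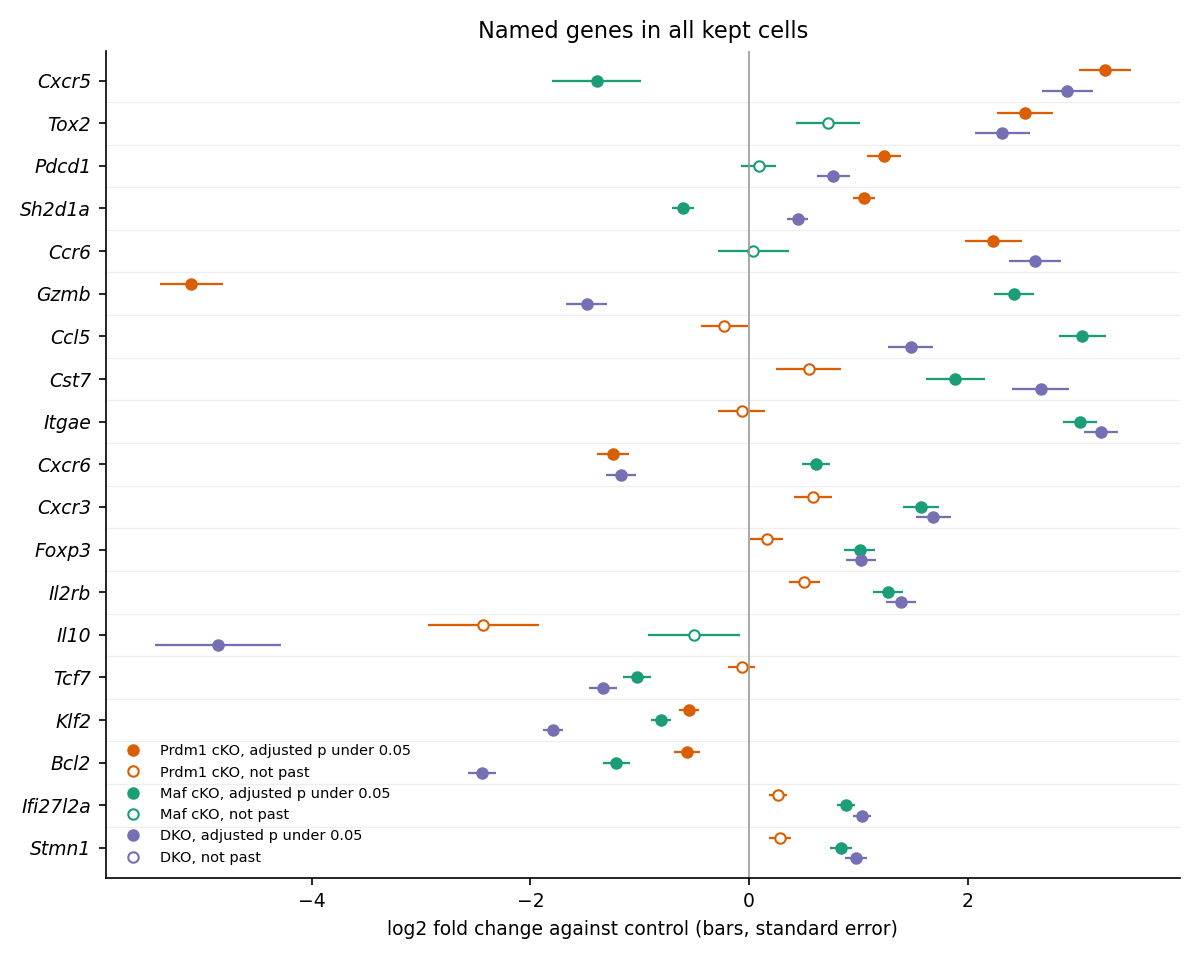
Log2 fold changes against control of 19 named genes in all kept cells for Prdm1 cKO, Maf cKO and DKO; points are edgeR estimates, bars are SE, and filled points have an adjusted p under 0.05. Gzmb fell by 5.10 in Prdm1 cKO, rose by 2.43 in Maf cKO and fell by 1.49 in DKO.

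The comparison of DKO with control asked what changes when both genes are targeted. Il10 fell 29-fold (log2 -4.86 ± 0.58, adjusted p = 0.00402), from 101 to 3.44 CPM with 2 libraries per group, and the call held in each alternative that kept them. Serpina3g, a protease inhibitor gene of activated T cells, rose 24.5-fold (4.62 ± 0.58, adjusted p = 0.00479), and Car2, which encodes carbonic anhydrase 2, rose 13.7-fold (3.78 ± 0.52, adjusted p = 0.00561). Itgae rose 9.33-fold (3.22 ± 0.15, adjusted p = 3.38e-11) and Cxcr5 rose 7.53-fold (2.91 ± 0.23, adjusted p = 6.39e-08). By edgeR quasi-likelihood 3800 of 10221 tested genes changed, 1950 up and 1850 down, 2342 of them by at least 1.5-fold. The count was 2301 without control replicate 2, and 1331 when naive-like cells were left out.

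Further genes passed in DKO. Tox2 (log2 2.32 ± 0.25, adjusted p = 2.54e-05) and Ccr6 (2.61 ± 0.24, adjusted p = 2.03e-07) rose, and so did Il23r, the receptor for IL-23 (4.12 ± 0.73, adjusted p = 0.000248, from 0.275 to 5.16 CPM). Irf4, a factor of activated T cells, rose by 1.11 ± 0.13 (adjusted p = 4.36e-06) and Cxcr3 by 1.69 ± 0.16 (adjusted p = 1.67e-05). The cytotoxic gene Cst7 (2.67 ± 0.26, adjusted p = 0.000574) and Plac8, a gene of monocytes and effector T cells (3.45 ± 0.37, adjusted p = 0.00281), rose. The cytokine gene Lta rose by 2.27 ± 0.19 (adjusted p = 6.68e-07) and the TNF receptor adaptor Traf1 by 1.31 ± 0.10 (adjusted p = 1.68e-08). Falls were found for Pdlim4 (-3.29 ± 0.16, adjusted p = 4.09e-11), Sox4 (-2.90 ± 0.19, adjusted p = 5.44e-08), Klf2 (-1.79 ± 0.09, adjusted p = 1.32e-10), Lef1 (-1.73 ± 0.11, adjusted p = 2.62e-09) and Bach2 (-2.43 ± 0.18, adjusted p = 1.03e-08). Tcf7 (-1.34 ± 0.13, adjusted p = 1.08e-05) and Cxcr6 (-1.17 ± 0.14, adjusted p = 5.91e-06) fell too.

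Within the fixed panel, Foxp3 rose 2.03-fold in DKO (log2 1.02 ± 0.14, adjusted p = 5.64e-05) and was at 0.02 (adjusted p = 0.941) without naive-like cells. Pdcd1 (0.77 ± 0.15, adjusted p = 0.00059; -0.18, adjusted p = 0.441 without naive-like cells) and Bcl6 (1.88 ± 0.42, adjusted p = 0.0018; 0.98, adjusted p = 0.153 without naive-like cells) rose in all cells. Gata3 fell by -0.53 ± 0.09 (adjusted p = 0.000201; -0.23, adjusted p = 0.105 with other lineages kept). Gzmb fell by -1.49 ± 0.19 (adjusted p = 0.00105; adjusted p = 0.0527 by limma on the mean of per-cell CPM). Il17a (-0.72, adjusted p = 0.479), Tigit, an inhibitory receptor gene (0.62, adjusted p = 0.287), and Icos (0.14, adjusted p = 0.227; -0.36, adjusted p = 0.0343 without naive-like cells) did not pass. The macrophage genes C1qa (-2.78 ± 0.31, adjusted p = 1.92e-06), C1qb (-2.92 ± 0.40, adjusted p = 8e-05) and C1qc (-2.92 ± 0.30, adjusted p = 6.01e-07) also fell, so remaining macrophage RNA was lower in the kept DKO cells.

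In DKO 14 of 25 lists passed camera, 10 up and 4 down. Naive and central memory genes fell in 14 of 17 (15 adjusted over the list alone; adjusted p = 2.08e-29; adjusted p = 0.206 with an estimated correlation). The next lists had an adjusted p = 0.49 with an estimated correlation. Cell cycle genes rose in 18 of 22 (19 adjusted over the list alone; adjusted p = 8.92e-12), such as Stmn1, a tubulin regulator of dividing cells (0.98 ± 0.10, adjusted p = 7.55e-07). Oxidative phosphorylation genes rose in 18 of 22 (19 adjusted over the list alone; adjusted p = 1.84e-06), such as Atp5j and Cox5b, and glycolysis genes in 11 of 16, with Eno1 falling (13 adjusted over the list alone; adjusted p = 1.91e-05). Without naive-like cells 5 of 22 cell cycle, 9 of 22 oxidative phosphorylation, 5 of 16 glycolysis and 5 of 14 cytotoxic genes rose and 9 of 17 naive and central memory genes fell. Cytotoxic genes rose in 9 of 14, with Gzmb falling (11 adjusted over the list alone; adjusted p = 0.000508), and Th1 genes in 10 of 16, with Cxcr6 falling (11 adjusted over the list alone; adjusted p = 0.000523; adjusted p = 0.302 without naive-like cells). Myeloid genes fell in 5 of 9, with Cst3 rising (6 adjusted over the list alone; adjusted p = 0.00504). Cst3 was at -0.99 (adjusted p = 0.00067) with other lineages kept. Tfh genes rose in 9 of 14 and fell in 2 (11 adjusted over the list alone; adjusted p = 0.00554), with adjusted p = 0.0861 without control replicate 1 and 0.184 without naive-like cells. The list of IL-10 and co-inhibitory receptors moved up although Il10 fell, since Pdcd1, Havcr2, Cd200, Cd274, Ctla2a, Cd160, Cd5 and Lag3 rose (8 of 14; 10 adjusted over the list alone; adjusted p = 0.0152). It had adjusted p = 0.851 without control replicate 1 and pointed down without naive-like cells (adjusted p = 0.404).

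The other DKO lists past the threshold had an adjusted p = 0.608 with an estimated correlation. NF-kB genes rose in 11 of 19 and fell in 2 (14 adjusted over the list alone; adjusted p = 0.000857; pointing down with adjusted p = 0.493 without naive-like cells). Interferon response genes rose in 12 of 24 and fell in 3, Ifit2, Rtp4 and Oasl2 (15 adjusted over the list alone; adjusted p = 0.0101), with adjusted p = 0.0761 without DKO replicate 1 and pointing down without naive-like cells (adjusted p = 0.92). Ribosomal protein genes fell in 18 of 28, with Rps12 rising (23 adjusted over the list alone; adjusted p = 0.000277). Scaled by library totals 13 fell and 1 rose, and without naive-like cells 7 rose and 0 fell by edgeR (camera up, adjusted p = 7.22e-06). With other lineages kept that list did not pass (adjusted p = 0.952). The mitochondrial genome fell in 9 of 13 (10 adjusted over the list alone; adjusted p = 0.00554; 7 fell by library totals; adjusted p = 0.667 without naive-like cells). Effector cytokine genes rose in 5 of 11, Lta, Csf1, Tnf, Ifng and Il2, and Areg fell (6 adjusted over the list alone; adjusted p = 0.048). With other lineages kept, Tnf was at -0.75 (adjusted p = 0.00564). The adjusted p of that list was 0.27 and 0.0991 without control replicates 1 and 2, 0.0838 and 0.0837 without Prdm1 cKO replicates 1 and 2, 0.0676 and 0.146 without Maf cKO replicates 1 and 2, and 0.701 without DKO replicate 1. It was 0.43 without naive-like cells, 0.0548 with RLE size factors and 0.0563 with a replicate block.

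The remaining 11 lists did not pass in DKO. Among them were Th17 (7 of 16 rose, 5 fell; adjusted p = 0.111), Th2 (3 of 8 rose, 2 fell; 0.807), Treg core (8 of 20 rose, 3 fell; 0.103), intestinal Treg (6 of 17 rose, 7 fell; 0.278), tissue residence (6 of 15 rose, 5 fell; 0.307) and chemokine (6 of 20 rose, 6 fell; 0.416). The others were immediate early (4 of 21 rose, 9 fell; 0.0596), IL-2 and STAT5 (4 of 15 rose, 5 fell; 0.321), survival (5 of 15 rose, 3 fell; 0.564), cholesterol synthesis (1 of 16 rose, 5 fell; 0.38) and transcription factor genes (14 of 25 rose, 7 fell; 0.0834). Of these, 7 passed downward by camera without naive-like cells: Treg core (1 rose, 9 fell; median -0.66; adjusted p = 9.03e-08), intestinal Treg (4 rose, 9 fell; median -1.08; adjusted p = 1.12e-05), Th2 (adjusted p = 0.0101), chemokine (0.0295), immediate early (0.000347), IL-2 and STAT5 (0.0094) and cholesterol synthesis genes (0.0313). Treg core and intestinal Treg genes passed upward without DKO replicate 2 (adjusted p = 0.00679 and 0.0492) and with other lineages kept (0.00723 and 0.0154), so no direction is given for them. Transcription factor genes passed upward without DKO replicate 2 (0.00235), without Prdm1 cKO replicate 1 or 2 (0.0455 and 0.0294) and with other lineages kept (0.0005), and Th17 genes without DKO replicate 2 (0.0244). Immediate early genes also passed downward without control replicate 1 (0.0092), DKO replicate 1 (0.00764) or Prdm1 cKO replicate 1 or 2 (0.0442 and 0.0418) and with other lineages kept (1.63e-06). In the Th17 list Ccr6, Irf4, Rora and Il23r rose while Ltb4r1 and Ccl20 were among those that fell. For intestinal Treg (median -0.36, mean -0.20) and Th2 genes (-0.45, -0.25) camera pointed up against a negative median and mean, and for chemokines the median (-0.12) was negative while the mean (0.12) and the test were positive.

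**Figure D3:**
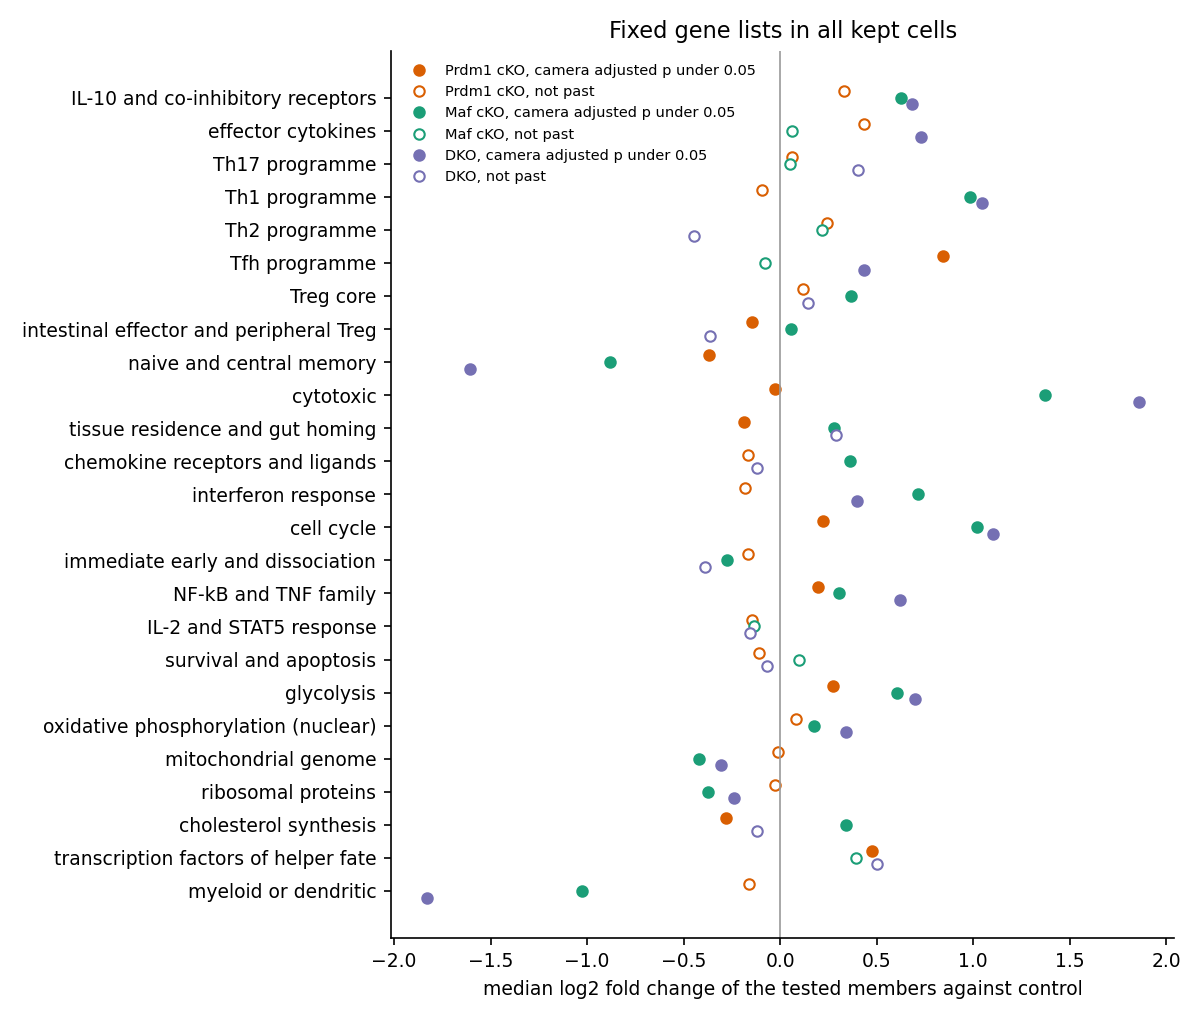
Median log2 fold change of each of the 25 tested lists in Prdm1 cKO, Maf cKO and DKO against control in all kept cells; filled points passed camera with a preset correlation. The naive and central memory list lay at -0.37, -0.88 and -1.61, and ribosomal and mitochondrial lists depend on scaling and on naive-like cells.

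The comparisons of DKO with each single knockout asked how DKO differs from each. Against Maf cKO, Cxcr5 rose by log2 4.31 ± 0.24 (adjusted p = 7.65e-09) and Tox2 by 1.59 ± 0.20 (adjusted p = 0.000415), while Gzmb fell by -3.91 ± 0.20 (adjusted p = 5.24e-05), with 2 libraries per group. Against Prdm1 cKO, Gzmb rose by 3.62 ± 0.30 (adjusted p = 0.000232), Itgae by 3.29 ± 0.15 (adjusted p = 4.13e-11) and Havcr2, which encodes the inhibitory receptor TIM-3, by 1.77 ± 0.31 (adjusted p = 0.00106). Sox4 (-2.75 ± 0.19, adjusted p = 1.86e-07) and Tcf7 (-1.27 ± 0.13, adjusted p = 3.56e-05) fell against Prdm1 cKO. By edgeR 2670 genes differed from Prdm1 cKO (1349 up, 1321 down) and 1036 from Maf cKO (461 up, 575 down). These counts were 1186 without Prdm1 cKO replicate 1, 1772 and 1546 without DKO replicates 1 and 2 for the former. For the latter they were 597, 414, 512 and 556 without Maf cKO replicates 1 and 2 and DKO replicates 1 and 2.

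For Il10 in all cells the difference of DKO from Maf cKO was log2 -4.36 ± 0.58 (adjusted p = 0.0192), but adjusted p was 0.0815 and 0.101 without Maf cKO replicates 1 and 2, and 0.128 and 0.131 without DKO replicates 1 and 2. The difference from Prdm1 cKO was -2.43 ± 0.71 (adjusted p = 0.0768). No call is drawn from fits without a control library, since the spread between the control libraries then leaves the shared estimate. The interaction, which tests whether DKO departs from the sum of the single effects, was -1.93 ± 0.83 for Il10 in all cells (adjusted p = 0.701). It was at -1.42 without control replicate 1 and at -2.68 without control replicate 2, fits from which no call is drawn for the same reason. Over all genes 17 passed the interaction by edgeR, 5 up and 12 down. That count was 11 without control replicate 2, 39 without Prdm1 cKO replicate 2, 41 without Maf cKO replicate 1, 10 without DKO replicate 1 and 6 without DKO replicate 2.

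Cell classes asked which T-cell states made up each group. Naive-like cells made up 65.7% ± 0.57 of kept cells in control, 50.2% ± 4.79 in Prdm1 cKO, 36.9% ± 3.29 in Maf cKO and 14.2% ± 0.17 in DKO (SD, n = 2). Their share fell in DKO (log2 -2.20 ± 0.21, edgeR adjusted p = 0.000135), and the share of cycling cells rose there, from 1.8% ± 0.31 to 10.1% ± 3.45 (2.48 ± 0.37, adjusted p = 0.000981). The Tfh-like class made up 2.24% ± 1.63 in control, 19.6% ± 4.12 in Prdm1 cKO, 0.18% ± 0.15 in Maf cKO and 0.48% ± 0.33 in DKO. Its share rose in Prdm1 cKO (3.11 ± 0.60, adjusted p = 0.00924), with adjusted p = 0.0782 without Prdm1 cKO replicate 2. It was 2.53 and 4.15 without control replicates 1 and 2. In Prdm1 cKO the other 5 shares did not pass, but the fall of Th1-like cells (-1.09 ± 0.51, adjusted p = 0.192) did without DKO replicate 1 or 2 (adjusted p = 0.0315 each).

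In Maf cKO the share of Tfh-like cells fell (log2 -3.52 ± 0.85, adjusted p = 0.00998), that of cycling cells rose to 6.12% ± 0.80 (1.76 ± 0.37, adjusted p = 0.00998), and that of naive-like cells fell (-0.83 ± 0.20, adjusted p = 0.00998; adjusted p = 0.261 with TMM over classes). For Tfh-like and cycling cells adjusted p was 0.0517 without control replicate 2 and 0.0549 without Maf cKO replicate 1, and for naive-like cells it was 0.0504 and 0.0631 without control replicates 1 and 2 and 0.0549 without Maf cKO replicate 1. The change of Tfh-like cells in Maf cKO was -4.11 and -2.48 without control replicates 1 and 2, -4.78 without Maf cKO replicate 2, and -1.56 and -1.72 at resolutions 0.6 and 1.4. Treg-like cells made up 16.4% ± 3.86, 12.1% ± 0.03, 10.7% ± 3.09 and 11.6% ± 0.81 in control, Prdm1 cKO, Maf cKO and DKO, and no comparison of them with control passed (adjusted p = 0.215, 0.0701 and 0.154). Outside the named classes, 1 cluster held 34.6% ± 5.51 of DKO cells and 0.21% ± 0.30 of control cells, with Car2, Prdm1, Serpina3g and Itgae among its leading genes. Another held 21.7% ± 1.35 of Maf cKO cells and 0.95% ± 0.68 of control cells. It was led by Gzmb, with Il10 and haemoglobin genes in its top 10. A Foxp3 UMI was found in 55.1% and 63.2% of cells of these clusters, the highest of all. Cells with a Foxp3 UMI numbered 237, 359, 750 and 1217 in control, Prdm1 cKO, Maf cKO and DKO (unequal depth, untested). Of them 75.9%, 34.8%, 21.2% and 17.7% lay in the Treg-like class. The Tfh-like class held 3.0% of them in control and 36.5% in Prdm1 cKO, so these parts differed by group.

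Other shares past the threshold depended on single libraries and on the method. Interferon-responding cells rose in Maf cKO (log2 1.28 ± 0.47, adjusted p = 0.0457), with adjusted p = 0.219 (0.78) without control replicate 2, 0.0629 without Prdm1 cKO replicate 1 or 2, and 0.143 and 0.0584 without Maf cKO replicates 1 and 2, while without control replicate 1 the change was 2.02. Its adjusted p was 0.0506 with the highest doublet scores left out and 0.0505 with a replicate block. In DKO, Th1-like cells rose (1.30 ± 0.47, adjusted p = 0.0454) and Tfh-like cells fell (-2.23 ± 0.71, adjusted p = 0.036). For Th1-like cells adjusted p was 0.201 without control replicate 2, 0.0878 without Prdm1 cKO replicate 1 or 2, 0.0808 without Maf cKO replicate 1 or 2 and 0.348 (0.44) without DKO replicate 2. For Tfh-like cells it was 0.204 (-1.20) without control replicate 2, 0.0755 without Prdm1 cKO replicate 1 or 2, 0.0595 without Maf cKO replicate 1 or 2 and 0.0895 without DKO replicate 2, while the change was -2.82 without control replicate 1 and -3.14 without DKO replicate 1. At resolutions 0.6 and 1.4 the Tfh-like change in DKO was -0.73 (adjusted p = 0.0543) and -0.71 (adjusted p = 0.125). The Th1-like rise in DKO did not pass with TMM over classes (0.95, adjusted p = 0.114), limma on logit shares (adjusted p = 0.0663) or a replicate block (adjusted p = 0.0664). In Maf cKO, Th1-like cells did not pass (1.07 ± 0.47, adjusted p = 0.0701). They did without DKO replicate 1 or 2 (adjusted p = 0.0121), with TMM over classes (1.31, adjusted p = 0.0315) and at resolutions 0.6 (adjusted p = 0.000148) and 1.4 (1.32, adjusted p = 0.016).

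**Figure D4:**
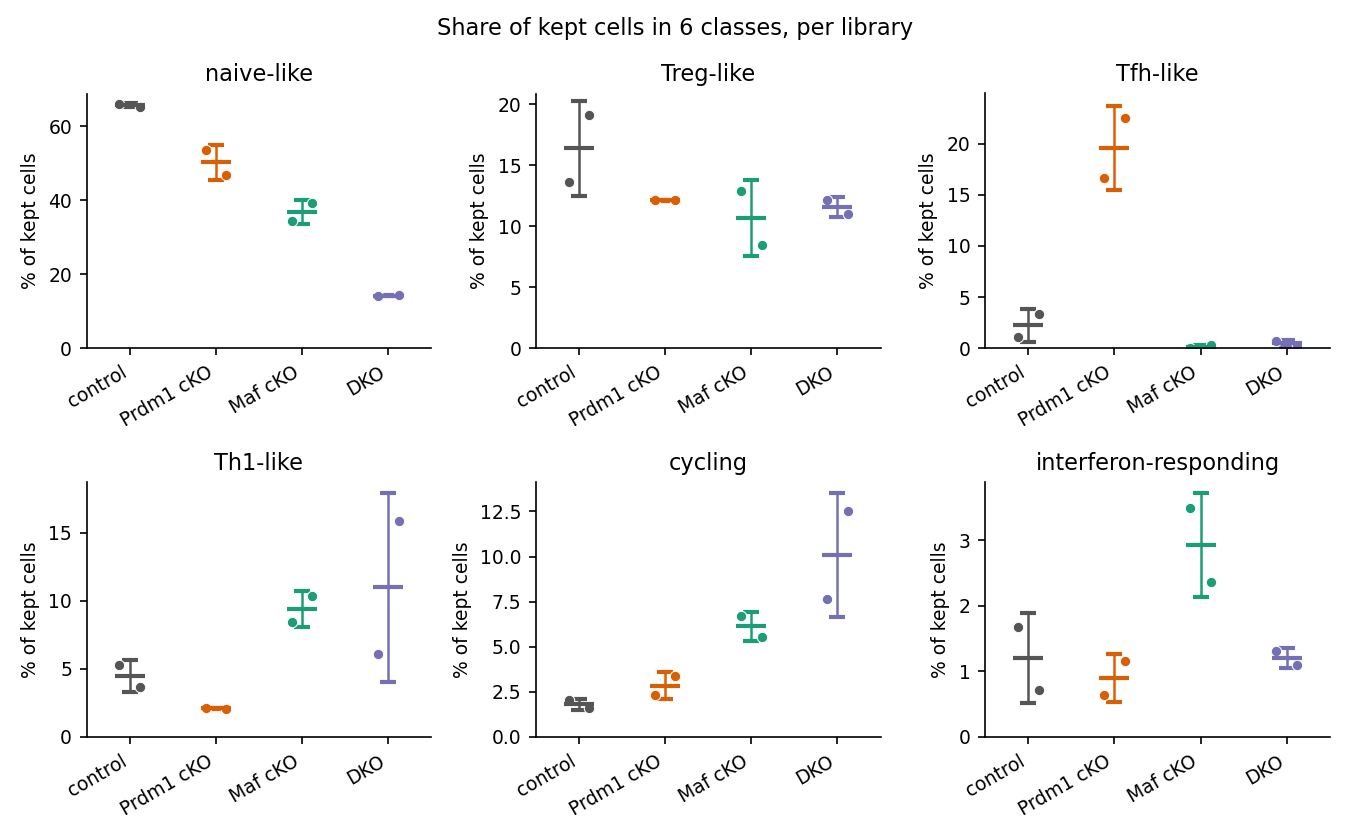
Percent of kept cells in each of 6 named classes in the 4 groups; points are libraries, and bars show the mean and SD of 2 libraries. Naive-like cells went from 65.7% in control to 14.2% in DKO, and Tfh-like cells made up 19.6% in Prdm1 cKO.

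Treg-like cells were compared to see which genes differed inside this class, where shifts between its clusters still enter. A cluster with Klrg1 and Areg as its leading genes held 108 and 185 cells of the control libraries and 60 and 50 of the DKO libraries, and a cluster led by Xcl1 and Ccl1 held 4 and 6 against 111 and 93. Il10 was at 463, 38.7, 104.3 and 4.3 CPM in control, Prdm1 cKO, Maf cKO and DKO (means of 2 libraries). In DKO it fell by log2 -6.73 ± 1.13 (adjusted p = 0.0181), with adjusted p = 0.0788 without control replicate 2 (-6.00), 0.127 without DKO replicate 1 (-6.09) and 0.102 without DKO replicate 2 (-7.85). Prdm1 cKO (-3.54 ± 0.89, adjusted p = 0.194) and Maf cKO (-2.12 ± 0.75, adjusted p = 0.477) did not pass for Il10. Foxp3 did not pass in Prdm1 cKO (-0.43, adjusted p = 0.208) or Maf cKO (0.08, adjusted p = 0.943). In DKO Foxp3 passed at -0.45 ± 0.16 (adjusted p = 0.0368), with 0.107 and 0.172 without control replicates 1 and 2, 0.0689 and 0.276 without DKO replicates 1 and 2, 0.204 by DESeq2, 0.144 with no filter on low counts, and 0.10 (adjusted p = 0.911) at resolution 0.6, so no direction is given for it. Car2 rose in Maf cKO (4.35 ± 0.67, adjusted p = 4.03e-05) and DKO (5.00 ± 0.57, adjusted p = 4.97e-09). Nav2 fell in both (-4.06 ± 0.46, adjusted p = 6.55e-08 and -4.30 ± 0.40, adjusted p = 2.76e-11), as did Rnase4, a secreted ribonuclease gene (-3.55 ± 0.51, adjusted p = 1.05e-05 and -6.39 ± 0.62, adjusted p = 8.71e-11).

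By edgeR 152 of 6287 genes changed in Treg-like cells of Prdm1 cKO, 105 in Maf cKO and 1549 in DKO. Leaving out libraries gave 70 without control replicate 2, 262 without Prdm1 cKO replicate 1 and 50 without Prdm1 cKO replicate 2 in the first. The second was 46, 54 and 60 without control replicate 2 and Maf cKO replicates 1 and 2, and the third 924 and 853 without control replicate 2 and DKO replicate 1. Several Treg genes depended on the resolution of the clusters. In DKO, Gata3 (-1.60 ± 0.19, adjusted p = 2.5e-08), Ctla4 (-1.22 ± 0.15, adjusted p = 5.61e-08) and Icos (-0.98 ± 0.14, adjusted p = 9.93e-07) fell at resolution 1.0. At resolution 0.6 they were at -0.96 (adjusted p = 0.116), -0.16 (adjusted p = 0.768) and 1.25 (adjusted p = 0.00269), so no direction is given for Icos. Against Maf cKO, Cxcr5 (4.09 ± 0.50) and Ccr6 (2.50 ± 0.36) rose and Klrg1, a receptor of terminal effector cells, fell (-2.70 ± 0.22, adjusted p = 1.52e-10).

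Among the non-Treg non-naive cells, Il10 fell 17.8-fold in DKO (log2 -4.15 ± 0.24, adjusted p = 4.8e-09), from 71 to 3.88 CPM with 2 libraries per group. Shifts between clusters enter here, as 1 cluster held 706 and 616 DKO cells but 5 and 0 control cells. Il10 was at 29.6 CPM in Prdm1 cKO (-1.23 ± 0.21, adjusted p = 0.00476; -0.99, adjusted p = 0.062 without control replicate 2) and at 95.2 CPM in Maf cKO (0.46 ± 0.17, adjusted p = 0.171). The Il10 interaction was -3.38 ± 0.30 (adjusted p = 9.41e-06), with shifts between clusters included, and no left-out library ended that call. It did not pass with classes at resolution 0.6 (-1.61, adjusted p = 0.892), with Treg cells set by a Foxp3 UMI (-2.36, adjusted p = 0.793) or with Treg-like cells included (-1.74, adjusted p = 0.847). Itgae rose in Maf cKO (2.85 ± 0.20, adjusted p = 1.22e-07) and DKO (2.80 ± 0.20, adjusted p = 5.64e-08), and Ccl5 rose in Maf cKO (1.90 ± 0.14, adjusted p = 1.53e-06). In Prdm1 cKO, Cxcr5 (2.76 ± 0.29, adjusted p = 3.13e-05) and Tox2 (2.24 ± 0.29, adjusted p = 0.00175) rose, while Gzmb (-4.82 ± 0.17, adjusted p = 2.63e-12) and Cxcr6 (-1.77 ± 0.14, adjusted p = 9.23e-07) fell. Ccr2, a chemokine receptor gene, fell in DKO (-3.48 ± 0.22, adjusted p = 1.88e-07).

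The non-Treg non-naive cells include the 2 clusters highest in Foxp3-positive cells, so they are not free of Treg cells. In them 133 of 9440 genes changed in Prdm1 cKO by edgeR, 336 in Maf cKO and 731 in DKO. Without control replicate 1 the first count was 33 and without Prdm1 cKO replicate 2 it was 53. The second was 76 without control replicate 2, 211 without Maf cKO replicate 1 and 142 without Maf cKO replicate 2. The third was 441 and 292 without control replicates 1 and 2 and 426 without DKO replicate 1. Naive-like cells held few changes, with 1 of 7820 genes past the threshold in Prdm1 cKO, 35 in Maf cKO and 68 in DKO.

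The share of cells with an Il10 UMI asked how many cells carried the transcript at equal depth. Thinned to 1500 UMIs per cell, 5.75% ± 3.39 of control cells had an Il10 UMI, against 1.54% ± 0.15 in Prdm1 cKO, 6.55% ± 0.24 in Maf cKO and 0.52% ± 0.11 in DKO (SD, n = 2, with 2366, 2710, 3119 and 3838 cells). Control was at 3.35% without control replicate 2 and at 8.15% without control replicate 1. In naive-like cells at the same depth of 1500 UMIs, which served as background, the shares were 0.26% ± 0.01, 0%, 0.11% and 0% of 1565, 1385, 1158 and 547 cells. The 0 counts allowed up to 0.46% and 0.68% in the Prdm1 cKO libraries and 1.46% and 1.32% in the DKO libraries (upper 95% Wilson bounds, counting error only). Among all cells but naive-like ones the shares were 16.5% ± 9.89, 3.15% ± 0.62, 10.4% ± 1.01 and 0.60% ± 0.13, and among cells with a Foxp3 UMI 29.2% ± 15.8, 3.11% ± 1.13, 16.8% ± 1.48 and 1.08% ± 0.83. These shares were not tested.

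**Figure D5:**
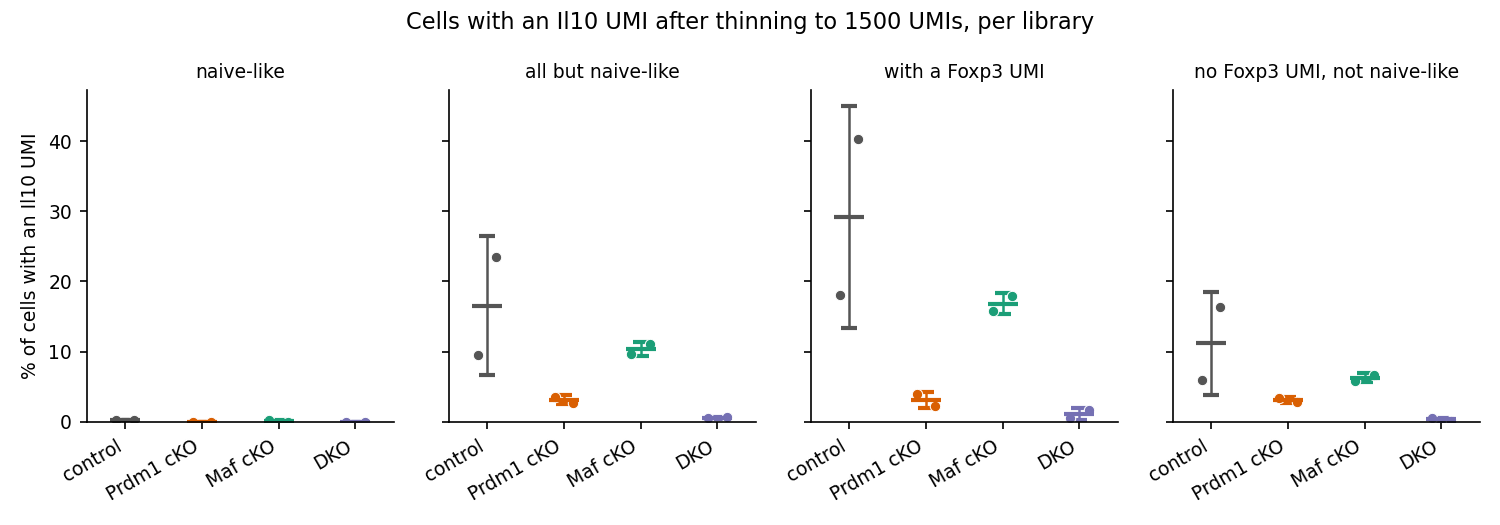
Percent of cells with an Il10 UMI after thinning to 1500 UMIs, in naive-like cells, all but naive-like cells, cells with a Foxp3 UMI, and other cells that are not naive-like; points are libraries, and bars show the mean and SD of 2 libraries. Among cells with a Foxp3 UMI the share was 29.2% in control and 1.08% in DKO.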

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

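The interaction was planned, while the comparison of macrophage-like cells and the tests of explanations below were chosen after the result was seen, apart from the test on monocyte-like cells.

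A difference between groups set the next genes apart: the interaction, which asks whether DKO departs from the sum of the single effects, passed by edgeR for 17 genes in all cells, with 2 libraries per group. Rab4a, a gene of endosome recycling, was at log2 1.56 ± 0.26 (adjusted p = 0.0119), with adjusted p = 0.0659 without control replicate 2, 0.0662 without Prdm1 cKO replicate 1 and 0.0726 without DKO replicate 2. Tmem208, a gene of protein transport, was at 0.86 ± 0.14 (adjusted p = 0.011), with 0.0714 without control replicate 1 and 0.0505 without DKO replicate 1. Sox4 was at -1.62 ± 0.26 (adjusted p = 0.0146), with 0.11 and 0.0659 without control replicates 1 and 2 and 0.0972 and 0.0554 without DKO replicates 1 and 2. Ly6c1, a surface protein gene of memory T cells, was at -1.29 ± 0.18 (adjusted p = 0.00392) and Cd81, a membrane protein gene, at -1.18 ± 0.16 (adjusted p = 0.00234), and no left-out library ended either call. Ly6c1 was at -1.04 (adjusted p = 0.262) and Cd81 at -1.36 (adjusted p = 0.234) with other lineages kept. Pdlim4 was at -1.20 ± 0.22 (adjusted p = 0.019), with 0.073 without control replicate 2, 0.0662 without Prdm1 cKO replicate 1, 0.204 without Maf cKO replicate 2, and 0.056 and 0.151 without DKO replicates 1 and 2. Nr3c1, the glucocorticoid receptor gene, was at -0.90 ± 0.18 (adjusted p = 0.0479), with 0.231 and 0.0659 without control replicates 1 and 2, 0.0866 without Prdm1 cKO replicate 1, 0.126 and 0.147 without Maf cKO replicates 1 and 2, and 0.056 and 0.197 without DKO replicates 1 and 2. Without naive-like cells the calls of these genes other than Cd81 ended, with adjusted p from 0.119 (Tmem208) to 0.893 (Pdlim4).

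The same interaction passed for 18 genes in Treg-like cells, and the calls named here ended when Treg cells were set by a Foxp3 UMI. Serinc3 was at log2 -2.03 ± 0.30 (adjusted p = 0.000277), Cd81 at -1.65 ± 0.26 (adjusted p = 0.000277) and Mt1, which encodes a metal-binding protein, at 3.23 ± 0.56 (adjusted p = 0.000964), and no left-out library ended these calls. Tnfsf8 was at -2.32 ± 0.43 (adjusted p = 0.00233; 0.124 without Maf cKO replicate 1) and Klrg1 at -1.67 ± 0.29 (adjusted p = 0.00233; 0.0739 without Prdm1 cKO replicate 1). Gata3 was at -1.33 ± 0.27 (adjusted p = 0.0106), with 0.221 without Prdm1 cKO replicate 1 and 0.0831 without Maf cKO replicate 1. Ecm1, a secreted matrix protein gene, was at -1.85 ± 0.37 (adjusted p = 0.007), with 0.137 without Prdm1 cKO replicate 1, 0.0568 without Maf cKO replicate 2 and 0.0954 without DKO replicate 1. Arl5a was at 1.84 ± 0.42 (adjusted p = 0.0383), with 0.314 without control replicate 2 (1.25), 0.174 without Prdm1 cKO replicate 1, 0.146 and 0.0633 without Maf cKO replicates 1 and 2, and 0.0954 without DKO replicate 1.

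In non-Treg non-naive cells 7 genes had an interaction. Pdlim1 was at log2 1.42 (0.343 without control replicate 1, 0.116 without Prdm1 cKO replicate 2, as adjusted p) and Satb1, a chromatin organiser, at 1.16 (adjusted p 0.227 and 0.114 without control replicates 1 and 2, 0.116 without Prdm1 cKO replicate 2, 0.125 without Maf cKO replicate 2). Cd81 was at -1.53, with adjusted p = 0.277 without control replicate 1, 0.116 without Prdm1 cKO replicate 2 and 0.125 without Maf cKO replicate 2. Rabgap1l was at -1.16, with adjusted p = 0.331 without control replicate 1, 0.0537 and 0.129 without Prdm1 cKO replicates 1 and 2, 0.182 without Maf cKO replicate 2 and 0.0804 without DKO replicate 2.

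Il10 in the non-Treg non-naive cells had an interaction of log2 -3.38 ± 0.30 (edgeR adjusted p = 9.41e-06), which was at -1.61 (adjusted p = 0.892) with classes at resolution 0.6. The Maf cKO level that enters it came mainly from the Foxp3-rich cluster led by Gzmb. In clusters with at least 20 cells in each control library, changed shares were argued against as the source of the low Il10 in DKO, since observed Il10 was at most 0.08 times that expected from the control level of each cluster. For whole DKO libraries changed shares cannot be told apart from lower Il10 per cell, as clusters with fewer control cells held the larger part of the DKO UMIs at resolution 1.0 and, with 0 expected there, the expected Il10 was 1.08 to 15.41 times the observed. Free RNA of macrophages was argued against, since 0.26% of control naive-like cells and 16.5% of the other control cells had an Il10 UMI at equal depth. The joint loss of Prdm1 and Maf, which the design names, stays among the open explanations as untested.

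Signals in cells that the comparisons leave out were found in the macrophage-like cells, where 109 of 8780 genes changed in Prdm1 cKO, 88 in Maf cKO and 583 in DKO by edgeR. Left-out libraries moved the first count to 45 and 68 without control replicates 1 and 2, 71 and 55 without Prdm1 cKO replicates 1 and 2. They moved the second to 58 and 21 without control replicates 1 and 2, and the third to 343 and 298 without control replicates 1 and 2 and 359 without DKO replicate 1. DESeq2 called 34, 51 and 286 genes, and with cells carrying a Cd3e UMI left out edgeR called 19, 53 and 477.

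Maf was at 281.7 CPM ± 2.1 in control macrophage-like cells, 297 ± 62.6 in Prdm1 cKO, 185.2 ± 13.4 in Maf cKO and 140.6 ± 15.2 in DKO (SD, n = 2), although CD4-Cre is used to delete in T cells. T-cell RNA in these cells was argued against, since it would bring 5.55 CPM of Maf against a difference of 141.1 CPM between control and DKO. More monocyte-like cells in DKO cannot be told apart from lower Maf per macrophage. Without cells carrying a Plac8, Ly6c2 or Ccr2 UMI the ratio of DKO to control was 0.742 (0.499 in all). It met the 0.75 bound set before, but single-library ratios, 0.709 to 0.776, spanned it. Cre activity in macrophages that express Cd4 cannot be told apart from other sources either, as 48.8% of control macrophage-like cells had a Cd4 UMI against 58.0% from a single Poisson mean, so that a Cd4 UMI does not separate expressing cells, although the ratio of DKO to control was lower without a Cd4 UMI (0.41) than with 1 (0.611), the reverse of what this Cre activity would give. An effect of the deletion in T cells on the macrophages around them, which the design would allow, stays open as untested.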

How the results depend on the processing

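Alternatives added after seeing the data were naive-like cells left out, Treg-like cells included, the highest doublet scores left out, the Tfh-like class left out, and those of macrophage-like cells. Of 353 alternative values of planned results, 254 stayed within 1.5 times or 1 SD of the reported value and 99 moved. Of 438 named gene calls, 174 held their direction and their side of the threshold in every alternative, 264 ended in at least 1, 161 ended when a library was left out, and 31 changed direction in at least 1 alternative. RLE size factors, the filters at 200 genes and 5% mitochondrial, Scrublet calls left out, the highest doublet scores left out and resolution 1.4 moved no count by over 1.5 times. For changes of direction the cause was not tested, and the same holds for the moved counts unless fewer libraries, cells or genes entered the test.

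Without a filter on low counts, which lets 16149 genes in, genes changed were 521 in Prdm1 cKO and 131 for the interaction in all cells, 162 in Treg-like cells of Maf cKO, and 377, 617 and 1120 in non-Treg non-naive cells of Prdm1 cKO, Maf cKO and DKO. With at least 1000 genes per cell they were 141 (Prdm1 cKO), 1175 (Maf cKO) and 11 (interaction), and with other lineages kept 53 (Prdm1 cKO) and 1064 (Maf cKO). A 1.5-fold minimum gave 151, 984 and 2342 in Prdm1 cKO, Maf cKO and DKO, 1447 for DKO against Prdm1 cKO and 615 for DKO against Maf cKO. DESeq2 gave 1007 (Maf cKO), 2346 (DKO), 1391 (DKO against Prdm1 cKO), 471 (DKO against Maf cKO), and 63, 57 and 606 in Treg-like cells of Prdm1 cKO, Maf cKO and DKO. Without naive-like cells the counts were 386 (Maf cKO), 1331 (DKO), 1047 (DKO against Prdm1 cKO), 653 (DKO against Maf cKO) and 5 (interaction). Limma on the mean of per-cell CPM gave 681 for DKO against Maf cKO, and library totals gave 30 for the interaction.

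Resolution 0.6 gave 36 and 226 genes in Treg-like cells of Prdm1 cKO and DKO and 1161 in non-Treg non-naive cells of DKO, which became 1331 with Treg-like cells included. Treg cells set by a Foxp3 UMI gave 99, 244 and 753 in Prdm1 cKO, Maf cKO and DKO, and 124 in non-Treg non-naive cells of Maf cKO. List counts by estimated correlation and by fry are given above. With the Tfh-like class left out, edgeR called 0 shares in Prdm1 cKO. The percent of cells with an Il10 UMI at 1000 UMIs, at 2000 UMIs and without thinning was 1.14, 2.09 and 3.06 in Prdm1 cKO, 4.65, 7.12 and 10.0 in Maf cKO, and 0.36, 0.65 and 1.54 in DKO, so depth sets how many cells show Il10.

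Leaving out each library in turn gave 66 to 357 changed genes in Prdm1 cKO, 739 to 2019 in Maf cKO, 2301 to 3970 in DKO, 1186 to 2670 for DKO against Prdm1 cKO, 414 to 1190 for DKO against Maf cKO and 6 to 41 for the interaction. In Treg-like cells the ranges were 50 to 262, 46 to 142 and 853 to 1734, and in non-Treg non-naive cells 33 to 141, 76 to 346 and 292 to 730, in Prdm1 cKO, Maf cKO and DKO. Lists past the threshold ranged over 8 to 15, 15 to 18 and 12 to 18, and changed shares over 0 to 2, 0 to 5 and 2 to 4. The percent of cells with an Il10 UMI ranged over 3.35 to 8.15 in control, 1.43 to 1.64 in Prdm1 cKO, 6.38 to 6.72 in Maf cKO and 0.44 to 0.60 in DKO, and its difference between control and DKO over 2.83 to 7.63.

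With naive-like cells left out the direction turned for Tcf7 in Prdm1 cKO (log2 0.61), Pdcd1 (-0.65), Tnfrsf4 (-0.064) and Cxcr6 (-0.15) in Maf cKO, and in DKO for Icos (-0.36), Pdcd1 (-0.18), Tnfrsf1b (-0.004), Crlf2 (-0.051), Capg (-0.19), Rps19 (0.16), Rpl13 (0.029), Rps24 (0.12) and Rpl8 (0.19), and for Tcf7 in DKO against Maf cKO (0.80). It turned with other lineages kept for Cst3 (-0.041) and Gpr34 (-0.39) in Maf cKO and for Cst3 (-0.99), Hk2 (-0.12) and Tnf (-0.75) in DKO. In Treg-like cells at resolution 0.6 it turned for Icos (1.21) and Tcf7 (-0.38) in Prdm1 cKO, Icos (0.69) in Maf cKO, and Icos (1.25) and Foxp3 (0.10) in DKO. It also turned for Icos (0.041) and Ccl5 (-0.06) in DKO against Prdm1 cKO, Foxp3 (0.11) in DKO against Maf cKO, and the interactions of Gata3 (0.084) and Tnfsf8 (3.93), and Foxp3 in non-Treg non-naive DKO cells was at -0.021. With Treg cells set by a Foxp3 UMI it turned for Ccl5 in Prdm1 cKO (0.003), Pdcd1 (0.90), Mt1 (-0.28) and Havcr2 (-0.019) in DKO against Maf cKO, and the interactions of Ecm1 (0.17) and Klrg1 (0.16). These values include changes past the threshold only in the alternative, and the cause was not tested.

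The replicate numbers 1 and 2 were not given as shared litters or batches, and deviations of same-numbered libraries correlated at -0.135 to -0.017 over 7048 genes, so the numbers do not pair the libraries. A replicate block gave 202, 1704, 3632, 2436, 922 and 16 changed genes in all cells for Prdm1 cKO, Maf cKO, DKO, DKO against Prdm1 cKO, DKO against Maf cKO and the interaction. It gave 126, 90 and 1467 in Treg-like cells, 97, 277 and 587 in non-Treg non-naive cells, 10, 17 and 13 lists, and 1, 3 and 3 shares. Libraries of a group differed beyond counting error by chi-square over degrees of freedom of 2.99 in control, 3.70 in Prdm1 cKO, 4.87 in Maf cKO and 4.08 in DKO. With 2 libraries per group no other split of the libraries was counted, and DKO cells were read at a median of 4219 UMIs against 2829 in control.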

Other observations

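The tests in this section were chosen after the result was seen.

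Genes changed in macrophage-like cells, by edgeR on 2 libraries per group. T-cell RNA was not excluded for Serpina3g and Il2rb. In DKO, Serpina3g rose by log2 3.37 ± 0.27 (adjusted p = 2.96e-06) and Nr1h3, which encodes the sterol sensor LXR-alpha, by 3.19 ± 0.31 (adjusted p = 1.26e-06). Fcrls, a gene of resident macrophages, fell by -2.49 ± 0.19 (adjusted p = 5.67e-07), Ecm1 by -1.94 ± 0.22 (adjusted p = 5e-06) and the heat shock gene Hspa1b by -1.91 ± 0.27 (adjusted p = 0.000303). Maf fell there by -0.93 ± 0.15 (adjusted p = 0.000346), and none of these calls ended without a library. In Prdm1 cKO, Il2rb rose (2.06 ± 0.31, adjusted p = 0.00042) and Ecm1 fell (-1.30 ± 0.17, adjusted p = 0.000163), and in Maf cKO, Ass1 of arginine synthesis rose (1.91 ± 0.26, adjusted p = 0.0005). The T-cell genes Cd3g (1.57), Ltb (1.70) and Tcf7 (2.21) rose in Prdm1 cKO, but with cells carrying a Cd3e UMI left out their adjusted p was 0.117, 0.192 and 0.571. The C1qa level was 5636.6, 5197.8, 5203.3 and 4502.1 CPM and the Cd3e level 46.3, 88.5, 72.9 and 67.0 CPM in control, Prdm1 cKO, Maf cKO and DKO.

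Il10 in macrophage-like cells was at 95.6 CPM ± 11.9 in control and 51.6 ± 5.6 in DKO (SD, n = 2; log2 -0.80, edgeR adjusted p = 0.00956). The call ended without control replicate 1 (-0.70, adjusted p = 0.0996), without DKO replicate 2 (-0.67, adjusted p = 0.105) and with cells carrying a Cd3e UMI left out (-0.58, adjusted p = 0.0982). Maf fell in Maf cKO macrophage-like cells (-0.62 ± 0.14, adjusted p = 0.0294). That call ended without control replicates 1 and 2 (adjusted p = 0.0949 and 0.212), without Maf cKO replicates 1 and 2 (0.249 and 0.0864), by DESeq2 (0.0559) and with Cd3e-carrying cells left out (0.283).

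Prdm1 counts were higher in the libraries labelled Prdm1 cKO and DKO than in control, the reverse of what loss of the whole transcript would give. In clusters with at least 20 cells in each control library, changed shares were argued against, since Prdm1 in each library of either group was at least 5.82 times that expected from the control level of each cluster. Exchanged labels of the Prdm1-deleted and Prdm1-intact groups cannot be told apart from a deleted allele that is still transcribed, because Maf, the other deleted gene, differed by a ratio of 1.57 between Prdm1 cKO and control, and no count by exon was used here. It is a hypothesis that a transcript without the floxed part is made in larger amount when Blimp-1 no longer represses its own gene, and reads over the floxed exons would test it. The Prdm1 deletion itself, which the design names, thus stays open as untested.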
